A study of Homo sapiens with 18 samples.

How the data were processed

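PolyA RNA-seq was available for 18 libraries of primary human pulmonary microvascular endothelial cells, in 6 groups of 3 with 1 library of each of 3 donors per group. The groups were 0.1% DMSO, 1 ng/ml TNF-alpha, and 100 nM of combretastatin A4, vinblastine, plinabulin or docetaxel, each for 6 h. The deposited values are a signal per gene and library that the authors obtained as gene counts divided by 1 size factor per library, as the deposited table itself shows. All values of a library are whole multiples of 1 step, and 100% of them gave whole reads within a tolerance of 1e-06. The size factors were 0.851 to 1.24, and the recovered totals 18.1 to 22.6 M reads. The submitters' processing notes name Trim Galore 0.6.6, FastQC 0.12.1, Salmon 1.8.0, STAR 2.7.9a, DESeq2 1.44.0 and the build GRCh38, without the role of each tool or the gene annotation. The 1 deposited table held 0 columns of other samples.

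The table listed 38900 genes, of which 35803 matched a symbol, 34971 were in GENCODE 29, from which positions on GRCh38 were taken, and 13752 were 0 in all libraries. XIST, TSIX and Y-linked genes (408) were left out of every step, because the cells are from human donors. Pseudogenes, antisense and HLA genes and loci without a symbol were tested but are not named. Genes that share reads with near-identical copies, such as some tubulins, are uncertain, since the authors' handling of shared reads is not recorded.

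The main test was limma 3.58.1 in R 4.3.3 with a trend in the variance prior, two-sided, on log2(signal + 1). It covered 15408 genes with a value of at least 10 in at least 3 libraries, fitted a mean per group to all 18 libraries (12 residual degrees of freedom), and called genes at a Benjamini-Hochberg adjusted p under 0.05. Groups came from the labels. The 10 comparisons were the 5 treatments against DMSO, the 3 pairs of destabilizers, and the mean of the destabilizers against docetaxel and against TNF-alpha. The tests, the lists, the alternatives and the rule for named genes were set before the data were examined. The design foresaw a normalized count, and the unit kept here is a signal, so count tests are alternatives and not the main test.

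The rule for named genes took, per comparison with DMSO or of the destabilizer mean, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 in the higher group and the same direction in 3 donors. Between destabilizers it took 5 each way. It also took up to 4 members with the smallest p of each gene list. Genes outside the rule are marked where they are named, apart from tubulin genes, all of which were drawn.

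Altogether 32 gene lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. They included lists for inflammation (NF-kB genes, adhesion molecules, chemokines, cytokines, interferon-stimulated genes), signalling (immediate early, MAPK feedback, MRTF-SRF, YAP and TAZ, Notch and BMP, TGF-beta and matrix genes), the cytoskeleton (tubulins, microtubule-associated proteins), vessel functions (junctions, endothelial identity, coagulation), the cell cycle, p53, stress (integrated stress response, heat shock, NRF2), metabolism (hypoxia, cholesterol, autophagy and lysosome), markers of mesenchymal, lymphatic, epithelial and leukocyte cells, and mitochondrially encoded and ribosomal protein genes. The results of 1 list and some genes are not reported here, though counts over all lists and genes include them.

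The donor numbers pair the samples, because the labels give the same donors in every group. Deviations of libraries from their group means correlated at 0.554 or more (median 0.620) within a donor and at -0.157 or less between donors, and 18 of 18 libraries were closest to one of the same donor. The block on donor (10 residual degrees of freedom) was chosen as an alternative from the start, and its values stand beside results where they change a call or move a count by over 1.5 times (for members of a list, the sum of both directions). No pair of libraries of a group was a duplicate, the chi-square per degree of freedom between recovered reads being 67.3 to 133.

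The alternatives were pseudocounts of 0.5 and 5, no filter or a stricter one (mean of at least 50), quantile normalization, upper-quartile rescaling, no trend in the variance prior, only the groups compared in the fit, the block on donor, each donor left out, an estimated correlation in camera, and edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 (Wald test) on the whole reads. Equal deposited totals, edgeR with the block on donor, and camera with an estimated correlation and the block were added after seeing the data. Shared controls were simulated in 50 sets of unchanged groups. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

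Each test was run on simulated reads for 15408 genes with 67, 67 and 66 genes changed by 1.5, 2 and 4 times in combretastatin A4 against DMSO. The limma test called 5.97%, 29.9% and 62.1% of them and 0 unchanged genes. With the block on donor the shares were 28.4%, 59.7% and 81.8%, with 7 unchanged genes called. edgeR gave 5.97%, 29.9% and 60.6%, with 0 unchanged genes, and DESeq2 16.4%, 46.3% and 71.2%, with 6. In simulated vinblastine against DMSO with no gene changed, limma with or without the block and edgeR called 0 genes and DESeq2 2. Camera called a list of 20 raised genes and did not call a list of 20 unchanged ones in the simulated combretastatin A4 comparison. The processing notes mention no molecular identifiers, so PCR copies may be among the reads counted.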

Results

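Gene expression was measured by polyA RNA-seq in primary human pulmonary microvascular endothelial cells, which line the small blood vessels of the lung. Cells of 3 donors were treated for 6 h in a serum-reduced medium, giving 18 libraries in 6 groups of 3 with 1 library of each donor per group. The groups received 0.1% DMSO (the solvent control), 1 ng/ml of the inflammatory cytokine TNF-alpha, or 100 nM of combretastatin A4, vinblastine, plinabulin or docetaxel. Combretastatin A4, vinblastine and plinabulin destabilize microtubules and are called destabilizers below, whereas docetaxel stabilizes them. The recovered read totals were 19.5 to 22.0 M with DMSO, 19.1 to 20.5 M with TNF-alpha, 18.1 to 22.6 M with combretastatin A4, 18.5 to 20.8 M with vinblastine, 19.1 to 21.4 M with plinabulin and 18.4 to 20.4 M with docetaxel.

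Levels are the deposited normalised read counts, given as mean ± SD over 3 libraries. Changes are differences of mean log2(normalised read count + 1) ± SE with 3 libraries per group, from 1 limma fit to all 18 libraries over 15408 genes, and this scale understates the change of genes with low values. Changes of gene lists are the mean log2 difference over members ± SD over 3 donors. The first 2 principal components, with 29.6% and 22.1% of the variance, parted the donors, and the third, with 12.0%, parted treatments. Changes are relative to the deposited scaling. Rescaling the libraries to equal totals moved the median change of all genes by -0.14 with TNF-alpha, -0.22 with combretastatin A4, -0.22 with vinblastine, -0.19 with plinabulin and -0.16 for destabilizers against docetaxel. Rescaling to equal upper quartiles moved it by -0.12 with combretastatin A4 and -0.12 with vinblastine. Under these rescalings and quantile normalization, 0 called genes passed the limma test in the other direction.

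With TNF-alpha, the comparison that sets the inflammatory reference, endothelial cells turned up genes that recruit and bind leukocytes. CXCL8, the chief neutrophil attractant, rose from 630.1 ± 610.3 to 29920.4 ± 3131 normalised read counts, a log2 change of 6.11 ± 0.68 (adjusted p = 9.85e-05, limma). CSF2, the gene of the growth factor GM-CSF, rose by 6.40 ± 0.57 on the log2 scale (adjusted p = 2.05e-05). SELE, VCAM1 and ICAM1, which slow and hold leukocytes on the vessel wall, rose by 6.00 ± 0.93, 5.64 ± 0.76 and 5.45 ± 0.88. NOS3, the endothelial nitric oxide synthase, fell by 2.60 ± 0.47, and LMCD1 and MAP2K6, a kinase upstream of p38, fell by 2.97 ± 0.42 and 3.31 ± 0.55.

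Of 18 measured NF-kB subunits and feedback genes, 16 rose with TNF-alpha, 0 fell and 2 did not pass the test, the same counts as when adjusted over the list alone. The mean change was 2.37 ± 0.181, with NFKBIA, the inhibitor that NF-kB itself induces, at 2.53 ± 0.17 and TNFAIP2 at 4.41 ± 0.30. Among 16 chemokines, 12 rose and 4 did not pass, 12 also when adjusted over the list alone (mean 3.57 ± 0.591), among them CX3CL1 at 5.02 ± 0.57 and CCL20 at 4.73 ± 0.63. Of 20 cytokines and colony-stimulating factors 7 rose and 13 did not pass, with 9 rising when adjusted over the list alone (mean 1.83 ± 0.134). EBI3 rose by 4.72 ± 0.49 and IL15 by 2.35 ± 0.28. These 3 lists were called by camera with the preset correlation (adjusted p = 4.52e-25, 5.34e-11 and 1.08e-05) and with an estimated one (adjusted p = 0.00861, 0.0408 and 0.0182), but not with an estimated one and the block on donor (0.0786, 0.141 and 0.0786). In the fit blocked on donor, 13 of the 20 cytokines rose.

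Interferon-stimulated genes were the next group with TNF-alpha: 17 of 36 rose, 0 fell and 19 did not pass, against 23 rising and 1 falling when adjusted over the list alone. IRF1, a transcription factor of the interferon response, rose by 2.92 ± 0.34, ISG20 by 2.77 ± 0.31 and GBP3 by 2.35 ± 0.31. The mean change was 2.19 ± 0.554, and camera's call (adjusted p = 1.74e-13) was lost at adjusted p = 0.135 with an estimated correlation. Of 13 leukocyte adhesion molecules 5 rose, 1 fell and 7 did not pass, as when adjusted over the list alone (mean 1.62 ± 0.406; adjusted p = 0.233 with an estimated correlation). Of 22 cholesterol synthesis and uptake genes 6 rose and 16 did not pass, 11 rising when adjusted over the list alone, with HMGCS1 at 1.06 ± 0.14, LSS at 0.87 ± 0.10 and SQLE at 1.51 ± 0.23. The mean was 0.47 ± 0.0972, and the call was lost at adjusted p = 0.233 with an estimated correlation. Of 25 endothelial identity and quiescence genes 4 fell, 0 rose and 21 did not pass, against 4 falling and 2 rising when adjusted over the list alone, with the receptor gene TIE1 at -0.52 ± 0.08 and EMCN at -1.50 ± 0.24. Their mean was -0.39 ± 0.0810, with adjusted p = 0.135 with an estimated correlation, and the call was also lost with equal upper quartiles (adjusted p = 0.0724, camera) and with equal totals (0.0953). Blocked on donor, 30 interferon-stimulated genes rose and 1 fell, 16 cholesterol genes rose, and 13 identity genes fell and 3 rose.

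In all, TNF-alpha raised 1091 genes and lowered 581 in the limma test, 65.3% of the calls being higher, against 55.6% with quantile normalization, 50.7% with equal upper quartiles and 40.3% with equal totals. With the donor as a block, 4881 genes were called (2588 higher, 2293 lower). Without donor 1, 2 or 3 the unblocked count was 958, 822 or 441. SELE and NOS3 were lost without donor 2 (adjusted p = 0.0534 and 0.0716, limma), their changes then being 6.04 and -2.55. VCAM1, ICAM1 and TIE1 were lost without donor 3 (0.0504, 0.0929 and 0.0560), at changes of 4.88, 5.02 and -0.49.

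**Figure D1:**
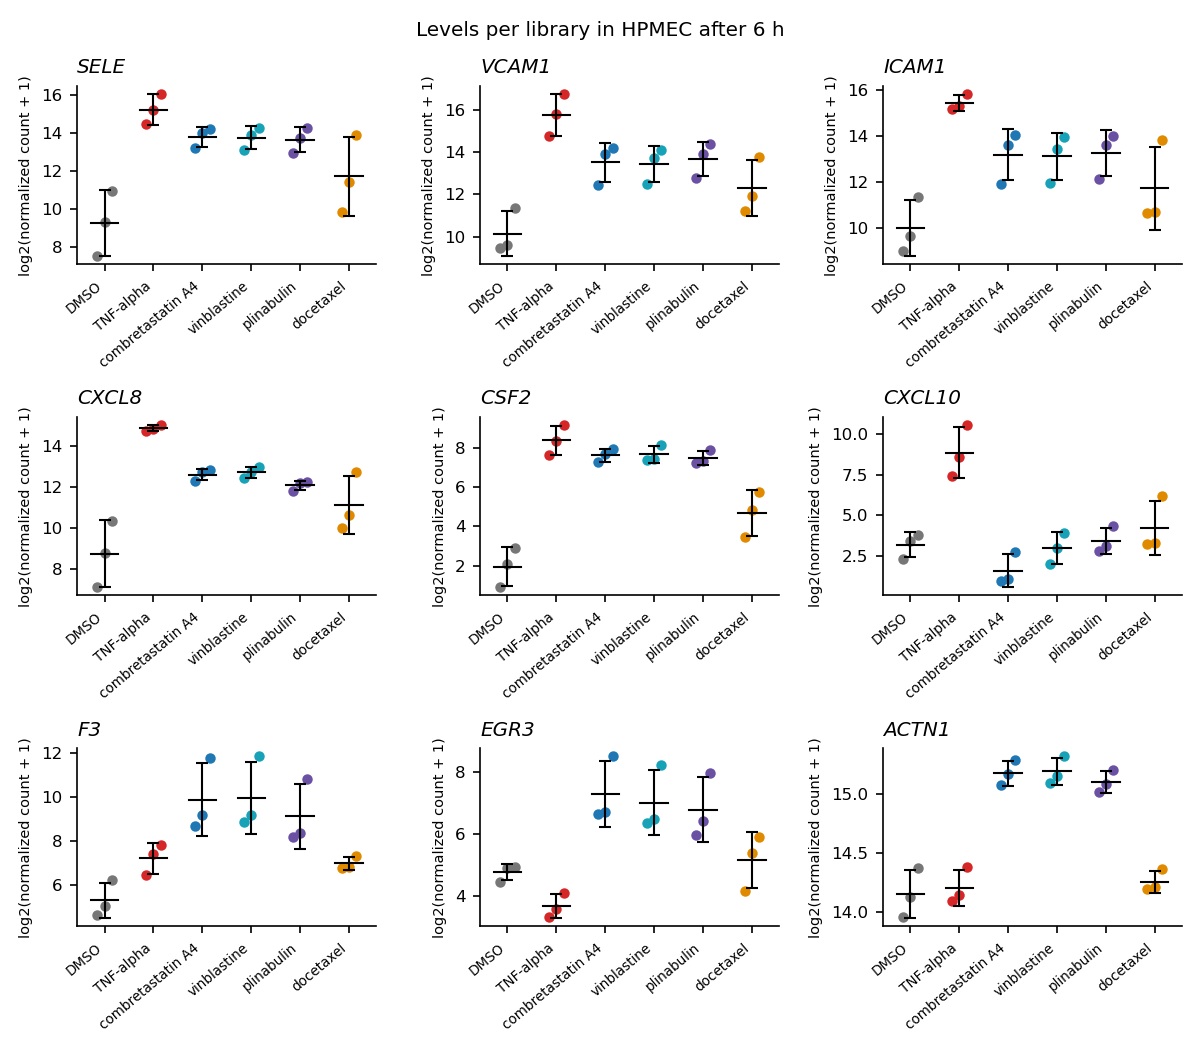
Log2(normalised read count + 1) (vertical axis) of 9 genes in the 6 groups (horizontal axis), with a point for each of 3 libraries and bars for mean ± SD on that scale. Without the logarithm, CXCL8 averaged 630.1 with DMSO, 29920.4 with TNF-alpha, 6322 with combretastatin A4 and 3143 with docetaxel, while ACTN1 averaged 18350.0 with DMSO, 18953 with TNF-alpha and 37081 with combretastatin A4.

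Combretastatin A4 against DMSO asks what depolymerizing microtubules does to the transcriptome. CSF2 rose by 5.64 ± 0.57 (adjusted p = 3.91e-05, limma), TRAF1, an adaptor of TNF receptors, from 464.98 ± 369.0 to 10468 ± 1243 normalised read counts or by 4.79 ± 0.56, and MMP10, a matrix metalloproteinase, by 4.66 ± 0.50. ACTN1, an actin crosslinker, rose by 1.02 ± 0.12 to 37081 ± 2718 normalised read counts. KLF15 fell by 3.82 ± 0.84, GJA4, an arterial gap junction gene, fell by 3.26 ± 0.56, and NOS3 fell by 1.86 ± 0.47.

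Combretastatin A4 changed 2667 genes in the limma test, 1563 higher and 1104 lower, 58.6% being higher, against 49.4% with quantile normalization, 38.6% with equal upper quartiles and 24.9% with equal totals. The block on donor gave 6036 calls (3108 higher, 2928 lower). Without donor 1, 2 or 3 the count was 1682, 1234 or 859, and with only these 6 libraries in the fit it was 886. GJA4 was lost without donor 3 (adjusted p = 0.0652, limma) and NOS3 without donor 1 (0.0720) or 2 (0.182). The changes were then -2.98 for GJA4 and -2.00 and -1.62 for NOS3.

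Vinblastine against DMSO puts the same question to a vinca alkaloid. CSF2 rose by 5.68 ± 0.57 (adjusted p = 3.84e-05, limma), TRAF1 by 4.71 ± 0.56 and MMP10 by 4.63 ± 0.50. CCL7, a monocyte attractant, rose by 4.60 ± 0.64 and LCP1, an actin-bundling protein, by 4.36 ± 0.60. GCNT1, a glycosyltransferase, fell by 3.54 ± 0.48 and CYP26A1, which degrades retinoic acid, fell by 3.40 ± 0.47. In total 1565 genes were higher and 1089 lower (58.97% higher), against 49.1% higher with quantile normalization, 38.3% with equal upper quartiles and 24.7% with equal totals. The block on donor gave 5938 calls, only these 6 libraries 849, and leaving out donor 1, 2 or 3 gave 1720, 1209 or 861.

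Plinabulin against DMSO does so for a diketopiperazine. CSF2 rose by 5.51 ± 0.57 (adjusted p = 6.54e-05, limma), TRAF1 by 4.63 ± 0.56 and MMP10 by 4.40 ± 0.50. NOD2, a sensor of bacterial wall fragments, rose by 3.91 ± 0.53. GCNT1 fell by 3.55 ± 0.48 and CYP26A1 fell by 3.70 ± 0.47. In total 1222 genes were higher and 764 lower (61.5% higher), against 51.7% higher with quantile normalization, 43.5% with equal upper quartiles and 27.8% with equal totals. The block on donor gave 5266 calls, DESeq2 2981, only these 6 libraries 414, and leaving out donor 1, 2 or 3 gave 1199, 676 or 531.

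The fixed gene lists showed which programmes the destabilizers shared, with values given in the order combretastatin A4, vinblastine, plinabulin. Of 18 NF-kB subunits and feedback genes, 16, 16 and 16 rose, the same numbers when adjusted over the list alone, with means of 1.91 ± 0.125, 1.88 ± 0.167 and 1.78 ± 0.209. NFKBIA rose by 1.58 ± 0.17, 1.62 ± 0.17 and 1.59 ± 0.17, and BIRC2, an inhibitor of apoptosis, by 1.35 ± 0.09, 1.28 ± 0.09 and 1.13 ± 0.09. Of 23 immediate early genes, which growth factors and stress switch on first, 17, 17 and 14 rose and 0 fell (20, 20 and 17 rising when adjusted over the list alone), with means of 1.48 ± 0.433, 1.42 ± 0.428 and 1.20 ± 0.405. ATF3 rose by 3.55 ± 0.42, 3.52 ± 0.42 and 3.01 ± 0.42. Of 23 MAPK feedback genes 9, 10 and 8 rose and 0 fell (when adjusted over the list alone 9, 11 and 10 rose and 0, 0 and 1 fell), including the phosphatase genes DUSP8 at 2.52 ± 0.24, 2.54 ± 0.24 and 2.35 ± 0.24 and DUSP10 at 2.81 ± 0.32, 2.69 ± 0.32 and 2.64 ± 0.32. Camera called these 3 lists in all 3 comparisons, also with an estimated correlation, where the largest adjusted p was 0.0359. With an estimated correlation and the block on donor all these calls were lost (adjusted p = 0.114, 0.122 and 0.0897 for NF-kB genes, 0.114, 0.122 and 0.0897 for immediate early genes and 0.0736, 0.0831 and 0.0897 for MAPK feedback genes). With the block 13, 13 and 10 MAPK feedback genes rose and 1, 1 and 1 fell.

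Genes controlled by the actin-sensing factors MRTF and SRF rose with each destabilizer: 20, 21 and 19 of 33, with 0 falling (22, 22 and 21 rising when adjusted over the list alone). TPM4, a tropomyosin, rose by 1.09 ± 0.13, 1.09 ± 0.13 and 1.01 ± 0.13, and PDLIM7 by 1.64 ± 0.21, 1.59 ± 0.21 and 1.51 ± 0.21. Means were 0.83 ± 0.101, 0.83 ± 0.133 and 0.77 ± 0.145, and camera's calls were lost at adjusted p = 0.0866, 0.0818 and 0.0842 with an estimated correlation. Of 34 microtubule-associated proteins and motors 11, 11 and 11 rose and 1, 2 and 1 fell (14, 13 and 12 rising and 1, 2 and 1 falling when adjusted over the list alone), with MAP1LC3B at 1.10 ± 0.09, 1.16 ± 0.09 and 1.03 ± 0.09 and MAP1B at 1.39 ± 0.14, 1.33 ± 0.14 and 1.12 ± 0.14. Means were 0.24 ± 0.105, 0.20 ± 0.110 and 0.18 ± 0.0827, turning to -0.03 with vinblastine and -0.01 with plinabulin under equal totals, and the calls were lost at adjusted p = 0.187, 0.236 and 0.249 with an estimated correlation. Quantile normalization also ended the calls for vinblastine and plinabulin (adjusted p = 0.0803 and 0.0780, camera), but not for combretastatin A4 (0.0375). Under the block on donor 15, 14 and 14 of these proteins and motors rose and 6, 7 and 5 fell.

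Inflammatory secretion and adhesion rose with the destabilizers in part. Of 16 chemokines 5, 5 and 5 rose and 0 fell, as when adjusted over the list alone, with CX3CL1 at 4.48 ± 0.57, 4.38 ± 0.57 and 4.50 ± 0.57 and CCL20 at 4.45 ± 0.63, 4.44 ± 0.63 and 4.13 ± 0.63 (means 1.85 ± 0.461, 1.92 ± 0.580 and 1.98 ± 0.644; adjusted p = 0.199, 0.193 and 0.143 with an estimated correlation). Of 20 cytokines 6, 6 and 5 rose and 0 fell (6, 6 and 7 rising when adjusted over the list alone; adjusted p = 0.126, 0.129 and 0.0850 with an estimated correlation), among them CSF2. Of 13 adhesion molecules 4, 5 and 5 rose and 1, 1 and 1 fell, as when adjusted over the list alone. SELE rose by 4.57 ± 0.93, 4.52 ± 0.93 and 4.40 ± 0.93. All 3 calls were lost without donor 2 (adjusted p = 0.108, 0.112 and 0.149, limma), though the changes were then 4.38, 4.27 and 4.12. That fit has fewer libraries and counts donor differences as residual spread. The adhesion calls were lost at adjusted p = 0.388, 0.321 and 0.290 with an estimated correlation, and with quantile normalization (0.205, 0.149 and 0.0999, camera). Of 36 interferon-stimulated genes 7, 7 and 7 rose and 2, 1 and 1 fell (8, 8 and 8 rising and 3, 2 and 2 falling when adjusted over the list alone), the list not being called in the main fit. With equal totals camera called it (adjusted p = 0.0267, 0.0116 and 0.0131), its means then being -0.12, -0.04 and -0.01. These lie above the shift of the median of all genes under equal totals, -0.22, -0.22 and -0.19. Camera sets a list against the other genes, so this was not a called fall. At the deposited scaling the list was not called with an estimated correlation. ISG20 rose by 2.23 ± 0.31, 2.29 ± 0.31 and 2.12 ± 0.31. In the fit blocked on donor, 11, 10 and 10 chemokines, 10, 10 and 10 cytokines, 7, 7 and 8 adhesion molecules and 8, 8 and 8 interferon-stimulated genes rose, while 1, 0 and 0, 3, 2 and 2, 2, 2 and 1, and 6, 4 and 5 fell.

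Of 28 TGF-beta targets and extracellular matrix genes 5, 5 and 5 rose with the destabilizers and 0 fell, as when adjusted over the list alone, among them LAMC1, a laminin chain, at 0.82 ± 0.14, 0.94 ± 0.14 and 0.81 ± 0.14 and SKIL at 0.72 ± 0.13, 0.73 ± 0.13 and 0.68 ± 0.13. This list's calls ended with quantile normalization (adjusted p = 0.199, 0.168 and 0.124, camera), while the values were adjusted p = 0.0601, 0.0645 and 0.0359 with an estimated correlation, the last call being lost when the block on donor was added (0.0897). Of 24 YAP and TAZ target genes 8, 9 and 4 rose and 1, 1 and 1 fell (9, 9 and 7 rising and 1, 1 and 1 falling when adjusted over the list alone), with LATS2 at 0.71 ± 0.13, 0.64 ± 0.13 and 0.66 ± 0.13. Those calls were lost at adjusted p = 0.388, 0.318 and 0.410 with an estimated correlation and with quantile normalization (0.205, 0.141 and 0.213, camera). Of 19 coagulation and fibrinolysis genes 5, 5 and 4 rose and 0 fell (when adjusted over the list alone 6, 6 and 6 rose and 1, 0 and 0 fell). This list was not called in the main fit but was with the block on donor (adjusted p = 0.0417, 0.0198 and 0.0466, camera) and with equal totals (0.0132, 0.00818 and 0.0207), and for the first pair with equal upper quartiles (0.0376 and 0.0213). It was not called with an estimated correlation (adjusted p = 0.199, 0.164 and 0.249) or with the block added to that (0.297, 0.206 and 0.282). F3, the tissue factor gene that starts coagulation, rose by 4.60 ± 0.92, 4.68 ± 0.92 and 3.83 ± 0.92. All 3 calls were lost without donor 1 (adjusted p = 0.0641, 0.0591 and 0.115, limma), at changes of 4.63, 4.74 and 3.98. That of plinabulin was also lost without donor 3 (0.0815), at a change of 4.65. Of 22 endothelial junction genes 3, 3 and 3 rose and 1, 1 and 1 fell (3, 4 and 3 rising and 2, 2 and 1 falling when adjusted over the list alone), with the junction adaptor AFDN at 0.91 ± 0.15, 0.91 ± 0.15 and 0.84 ± 0.15. Of 25 endothelial identity and quiescence genes 3, 3 and 3 fell and 0 rose, as when adjusted over the list alone, with the transcription factor ERG at -0.59 ± 0.15, -0.57 ± 0.15 and -0.56 ± 0.15, and camera called neither this list nor the junction genes. Blocked on donor, the members rising and falling were 15, 14 and 15 against 3, 3 and 2 for TGF-beta and matrix genes and 12, 13 and 11 against 2, 2 and 2 for YAP and TAZ targets. They were 10, 10 and 10 against 5, 5 and 5 for coagulation, 7, 6 and 6 against 5, 5 and 5 for junction genes and 6, 6 and 5 against 10, 8 and 7 for identity genes.

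Signs of RNA composition moved with the same groups. The 13 mitochondrially encoded genes had mean changes of 0.37 ± 0.0547, 0.37 ± 0.246 and 0.43 ± 0.167, with 0, 1 and 2 members called higher (0, 0 and 10 when adjusted over the list alone, 13, 13 and 13 with the block on donor). Camera called the list, but not with quantile normalization (adjusted p = 0.745, 0.685 and 0.184), and the values were adjusted p = 0.456, 0.454 and 0.393 with an estimated correlation. The 31 cytosolic ribosomal protein genes had means of -0.19 ± 0.176, -0.17 ± 0.0564 and -0.15 ± 0.0390, with 0 members called, also when adjusted over the list alone, and 18, 13 and 10 lower with the block on donor (adjusted p = 0.570, 0.675 and 0.670 with an estimated correlation for a call made at the preset one). Markers of other cell types were not called as lists. Of 11 mesenchymal and mural markers 1, 1 and 1 fell, PDGFRB at -2.79 ± 0.81, -3.17 ± 0.81 and -2.63 ± 0.81. Of 10 lymphatic endothelial markers 1, 1 and 0 rose, NRP2 being at 0.80 ± 0.22, 0.79 ± 0.22 and 0.56 ± 0.22 (with plinabulin adjusted p = 0.0317 with the block on donor). Of 9 epithelial markers 0, 0 and 1 fell, MUC1 being at -2.21 ± 0.87, -1.53 ± 0.87 and -2.88 ± 0.87, and of 5 leukocyte markers 1, 0 and 0 rose, LYZ being at 0.83 ± 0.27, 0.76 ± 0.27 and 0.73 ± 0.27 (the last pair at adjusted p = 0.0277 and 0.0382 with the block on donor). Under the block on donor 3, 3 and 3 lymphatic markers rose and 1, 1 and 1 fell, 2, 1 and 2 epithelial markers fell, and 1, 1 and 1 leukocyte markers rose.

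**Figure D2:**
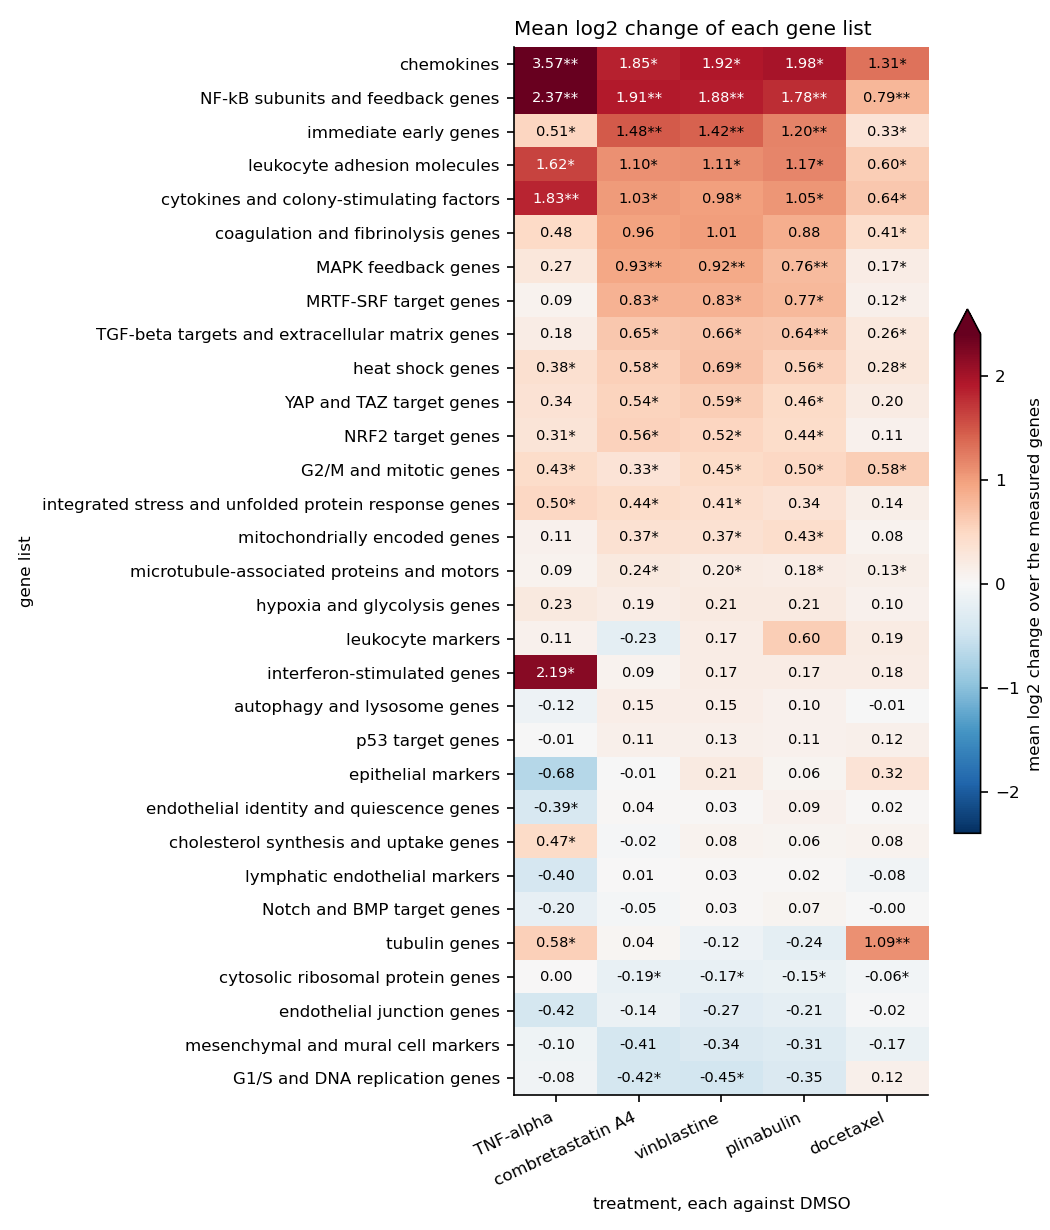
Mean log2 change against DMSO of the measured members of 31 gene lists (vertical axis) with each of 5 treatments (horizontal axis), as colour and printed value, with 1 star for lists called by camera with its preset correlation and 2 stars for those also called with an estimated one. NF-kB subunits and feedback genes carry 2 stars in all 5 treatments, with means of 2.37, 1.91, 1.88, 1.78 and 0.79, and tubulin genes carry 2 stars with docetaxel at 1.09.

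Docetaxel against DMSO asks whether stabilizing microtubules acts in the same way. The genes past the limma threshold were a pair of beta-tubulins: TUBB2B rose from 53.6 ± 6.53 to 192.1 ± 28.5 normalised read counts, by 1.82 ± 0.24 on the log2 scale, and TUBB6 from 7021 ± 1209 to 16261 ± 3132, by 1.21 ± 0.15 (adjusted p = 0.0149 for both). TUBB2B lies on chromosome 6 from 3224261 to 3231730 and TUBB6 on chromosome 18 from 12307669 to 12344320 (GRCh38). TUBB2A, at 1.84 ± 0.28, and TUBA1A, at 1.66 ± 0.27, did not pass (adjusted p = 0.0536 and 0.0883, limma), though both did with the block on donor (0.000202 and 0.000509). Some tubulin genes are near-identical copies of one another, so the reads of such members are uncertain.

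Of 14 measured tubulin genes, 2 passed the all-gene test with docetaxel and 8 rose when adjusted over the list alone, with a mean of 1.09 ± 0.409. Camera called the list (adjusted p = 3.88e-22), also with an estimated correlation (adjusted p = 0.00758) and with the block on donor added to it (0.0446). With combretastatin A4, vinblastine and plinabulin 1, 1 and 0 tubulin genes rose and 1, 1 and 0 fell, as when adjusted over the list alone. TUBB2B stood at 1.23 ± 0.24, 1.21 ± 0.24 and 0.74 ± 0.24, TUBA4A at -1.41 ± 0.44, -1.42 ± 0.44 and -1.25 ± 0.44, and the list was not called. The vinblastine call of TUBB2B was lost without donor 2 (adjusted p = 0.0768, limma), at a change of 0.96. With plinabulin neither passed in the main fit, and both did with the block on donor (0.0195 and 0.0184). With TNF-alpha 4 rose (5 when adjusted over the list alone; mean 0.58 ± 0.309; adjusted p = 0.287 with an estimated correlation), TUBB2B by 1.50 ± 0.24. In the fit blocked on donor, 9 tubulin genes rose with docetaxel and 9 with TNF-alpha, and with the destabilizers 4, 1 and 1 rose and 3, 4 and 4 fell.

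**Figure D3:**
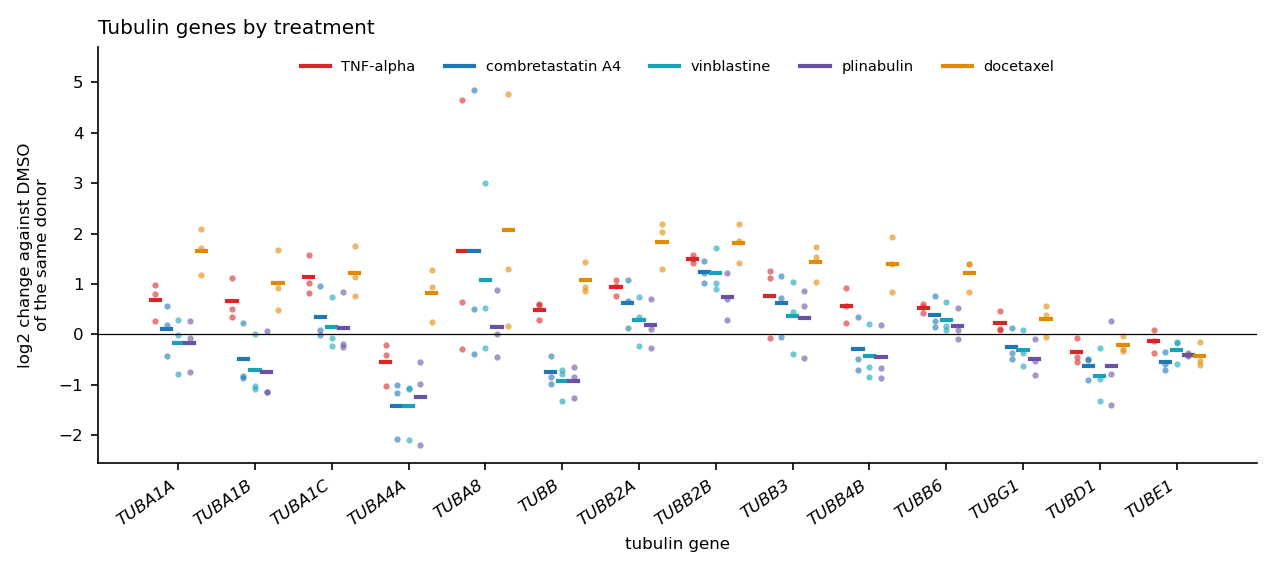
Log2 change against DMSO (vertical axis) of 14 measured tubulin genes (horizontal axis) with combretastatin A4, vinblastine, plinabulin, docetaxel and TNF-alpha, with a point for each of 3 donors (each against its own DMSO library) and a line at the mean. With docetaxel TUBB2A, TUBB2B and TUBA1A average 1.84, 1.82 and 1.66, while TUBB averages -0.75, -0.93 and -0.91 with the destabilizers and 1.09 with docetaxel.

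Inflammatory lists shifted with docetaxel without members passing the all-gene test. Of 18 NF-kB subunits and feedback genes 0 passed and 11 rose when adjusted over the list alone, with a mean of 0.79 ± 0.294 (camera, adjusted p = 3.88e-22; adjusted p = 0.00758 with an estimated correlation, lost at 0.0880 with the block on donor added). TNFAIP2 stood at 1.48 ± 0.30 and NFKBIA at 0.82 ± 0.17. Chemokines averaged 1.31 ± 0.396, with 0 of 16 past the all-gene test and 4 rising when adjusted over the list alone, and cytokines 0.64 ± 0.202, with 0 and 1 of 20 (adjusted p = 0.0524 and 0.0524 with an estimated correlation). CCL7 stood at 2.81 ± 0.64 and CSF2 at 2.71 ± 0.57. Blocked on donor, TNFAIP2, NFKBIA, CCL7 and CSF2 passed (adjusted p = 0.0374, 0.0288, 0.0359 and 0.0311, limma). G2/M and mitotic genes averaged 0.58 ± 0.517, with 0 of 33 passing either adjustment over all genes or adjusted over the list alone (camera, adjusted p = 9.37e-18; adjusted p = 0.171 with an estimated correlation), CCNB2 being at 0.88 ± 0.30. Coagulation genes averaged 0.41 ± 0.0943 with 0 of 19 passing, also when adjusted over the list alone (camera, adjusted p = 0.0337; adjusted p = 0.0893 with an estimated correlation). Camera called 15 of 32 lists, 14 up and 1 down, against 2 with an estimated correlation and 1 with the block on donor added. Other splits of these libraries called up to 18 lists, and at most 10 where each side held 1 library of each donor. Ribosomal protein genes averaged -0.064, called by camera with equal upper quartiles (adjusted p = 0.000660), quantile normalization (2.82e-10) and equal totals (2.17e-05). They were not called with an estimated correlation. Under the block on donor 4 NF-kB genes, 3 chemokines, 1 cytokine and 3 coagulation genes rose.

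The limma test called 2 genes higher and 0 lower with docetaxel, against 572 genes at an unadjusted p under 0.05, 2 by edgeR, 40 by DESeq2 and 84 with the block on donor (80 higher, 4 lower). Both tubulin genes were lost without donor 1, 2 or 3 (adjusted p = 0.278 to 1, limma, with TUBB2B at 1.63 to 2.02 and TUBB6 at 1.12 to 1.40) or with only these 6 libraries in the fit, where 0 genes were called. Of the lower genes under the block SLC40A1, INTS15 and BBS1 stood at -0.57, -0.40 and -0.45, named here after their values were seen, beside 1 locus without a symbol.

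The destabilizers shared most of their response. In the limma test, 1149 genes were higher with all 3 and 620 lower, against 12.6 and 3.87 for independent lists. Simulated unchanged groups that share simulated DMSO libraries gave 0 in a fit blocked on donor. With no gene changed hardly any gene is called, so this 0 does not measure the overlap that shared controls add. The 3 controls cannot be split, so part of the excess over independent lists may come from sharing them. The median change of the shared higher genes was 0.83 with combretastatin A4, 0.82 with vinblastine and 0.75 with plinabulin, and TNF-alpha moved the same genes by 0.51, with 590 of the higher and 271 of the lower genes also called with TNF-alpha (81.4 and 23.4 for independent lists, which leave out that TNF-alpha shares the controls too). The median change of the higher and lower genes with docetaxel was 0.25 and -0.24. The medians were 0.0186 and -0.0380 with docetaxel simulated as unchanged on shared controls that were simulated too. With docetaxel 0 of these genes were called by limma (59 and 1 with the block on donor). With the block, 4505 genes were called in 1 direction by all 3, and without 1 donor 478 to 1075.

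Across genes, which are not independent replicates, the log2 changes of combretastatin A4 and vinblastine correlated at r = 0.881 (rank correlation 0.889), of combretastatin A4 and plinabulin at 0.862 (0.876) and of vinblastine and plinabulin at 0.861 (0.875). The destabilizers correlated with TNF-alpha at 0.643, 0.647 and 0.656 (rank correlations 0.641, 0.647 and 0.661), with docetaxel at 0.573, 0.578 and 0.588 (0.641, 0.644 and 0.664), and TNF-alpha with docetaxel at 0.510 (0.563). Simulated unchanged groups set against 1 shared simulated control group gave r from 0.497 to 0.506. A shared control by itself fixes this value, so it does not measure what these DMSO libraries add. The covariances exceeded the simulated ones by 0.461, 0.423 and 0.423 among destabilizers, by 0.311, 0.315 and 0.300 with TNF-alpha, by 0.117, 0.1199 and 0.113 with docetaxel, and by 0.0950 between TNF-alpha and docetaxel. All 10 pairs of treatments were computed.

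**Figure D4:**
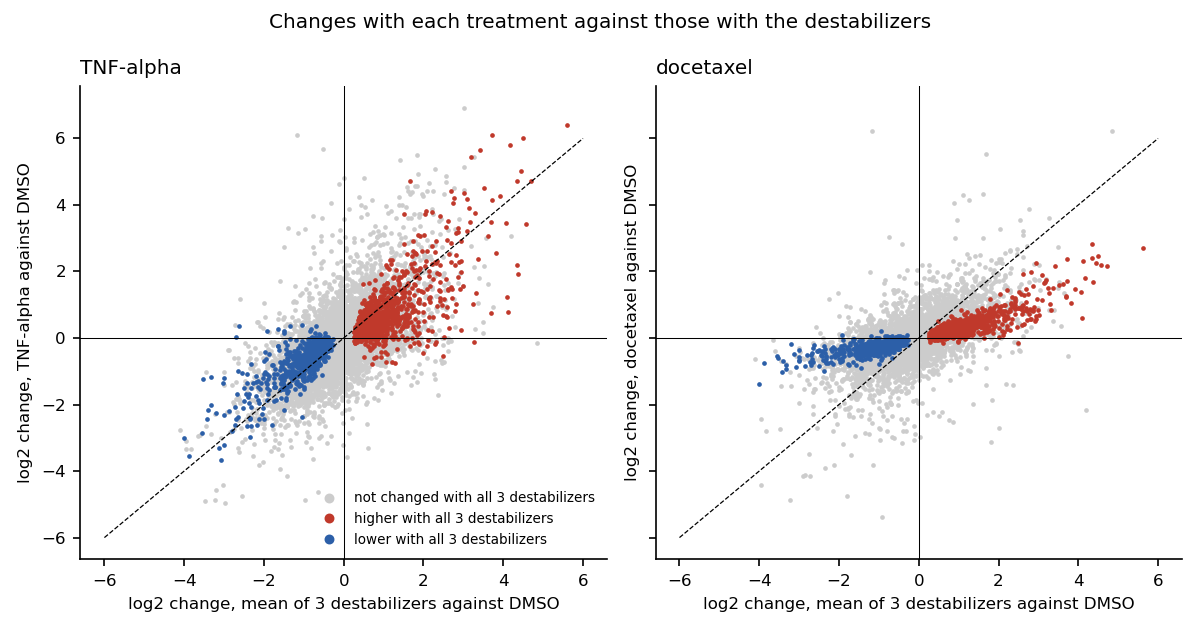
Log2 change against DMSO of each tested gene, with the mean of the 3 destabilizers on the horizontal axis and TNF-alpha or docetaxel on the vertical axis, where coloured points are genes called in 1 direction with all 3 destabilizers and the dashed line marks equal change. The 1149 shared higher genes have a median of 0.51 with TNF-alpha and 0.25 with docetaxel.

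Comparisons between the destabilizers set a stilbene (combretastatin A4), a vinca alkaloid and a diketopiperazine side by side at equal dose and time. CSF2 differed by -0.05 between combretastatin A4 and vinblastine (95% interval -1.28 to 1.19), by 0.12 between combretastatin A4 and plinabulin (-1.11 to 1.35) and by 0.17 between vinblastine and plinabulin (-1.06 to 1.40). ACTN1 differed by -0.01 (-0.27 to 0.24), 0.08 (-0.18 to 0.34) and 0.09 (-0.16 to 0.35). NPC1, a lysosomal cholesterol transporter, differed by 0.08 (-0.23 to 0.38), 0.38 (0.07 to 0.68) and 0.30 (0.00 to 0.60), and TUBB2B by 0.02 (-0.49 to 0.52), 0.49 (-0.01 to 1.00) and 0.47 (-0.03 to 0.98), each at adjusted p = 1 over all genes (limma). Over the 1769 shared genes the median absolute difference was 0.0510, 0.0906 and 0.0863. The median interval was 0.353 to each side, and the intervals of 1591, 1564 and 1557 genes lay within a 2-fold difference. These intervals and those above count donor differences as residual spread. With the block on donor the median interval was 0.256 to each side, and those of 1695, 1672 and 1682 genes lay within 2-fold. The shared genes were chosen for passing in 1 direction with all 3 compounds, which favours genes that the compounds move alike.

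Between combretastatin A4 and vinblastine limma called 0 genes, with 127 at an unadjusted p under 0.05, 0 by edgeR and 4 by DESeq2. SCAMP2, at -0.27, was among the last, named after its value was seen, beside 3 loci without a symbol. For combretastatin A4 against plinabulin the counts were 0 by limma, 194 unadjusted, 0 by edgeR and 2 by DESeq2, where FAM120C stood at -1.02, likewise named afterwards. For vinblastine against plinabulin they were 0, 173, 0 and 2, the last being loci without a symbol. Missing the threshold does not show that the compounds act alike.

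The mean of the destabilizers was then set against docetaxel, which asks how breaking and stabilizing microtubules differ. Tubulin genes stood lower with the destabilizers: 11 of 14 fell relative to docetaxel, 0 rose and 3 did not pass, as when adjusted over the list alone, with a mean of -1.19 ± 0.103. TUBB4B differed by -1.78 ± 0.19 (adjusted p = 0.000108, limma), TUBA1A by -1.74 ± 0.22 and TUBB6 by -0.92 ± 0.13. ACTN1 was higher with the destabilizers by 0.90 ± 0.10, DUSP8 by 2.13 ± 0.20, RRAD, a small GTPase, by 2.69 ± 0.32 and SQSTM1, an autophagy receptor, by 1.16 ± 0.11.

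Relative to docetaxel 16 of 18 NF-kB subunits and feedback genes were higher, as when adjusted over the list alone (mean 1.06 ± 0.458), with BIRC2 at 0.97 ± 0.08 and RELA at 0.63 ± 0.09. Immediate early genes were higher in 13 of 23 cases (18 adjusted over the list alone; mean 1.04 ± 0.303), JUNB by 1.47 ± 0.22, and MAPK feedback genes in 7 of 23 (when adjusted over the list alone 9 were higher and 1 lower; mean 0.70 ± 0.238). These 3 lists and the tubulin genes held with an estimated correlation (adjusted p = 0.0331, 0.0331, 0.0219 and 0.0333), but not when the block on donor was added (0.109, 0.106, 0.0914 and 0.106). MRTF-SRF target genes were higher in 19 of 33 cases (21 adjusted over the list alone; mean 0.69 ± 0.0786), CALD1 by 1.34 ± 0.18, and the call was lost at adjusted p = 0.0530 with an estimated correlation. Of 16 chemokines 14 did not pass, as when adjusted over the list alone (mean 0.61 ± 0.851). The chemokine list was not called in the main fit but was with the block on donor (camera, adjusted p = 0.0432), equal upper quartiles (0.0137), quantile normalization (0.0484) and equal totals (0.00273). It was not called with an estimated correlation (adjusted p = 0.460, or 0.518 with the block added). In the fit blocked on donor, 20 immediate early genes, 12 MAPK feedback genes and 6 chemokines were higher, and 0, 1 and 1 lower. RNA composition differed here too: mitochondrially encoded genes averaged 0.31 ± 0.0575, with 1 of 13 higher (1 adjusted over the list alone, 13 with the block), and ribosomal protein genes -0.11 ± 0.0412, with 0 of 31 lower (0 adjusted over the list alone, 2 with the block). Camera called both (adjusted p = 0.000220 and 0.0123), but neither with an estimated correlation (0.456 and 0.679), nor the mitochondrial list with quantile normalization (0.449).

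In total 1127 genes were higher and 744 lower with the destabilizers than with docetaxel (60.2% higher), against 53.1% higher with quantile normalization, 39.1% with equal upper quartiles and 23.2% with equal totals. The block on donor gave 5055 calls, DESeq2 2938, and leaving out donor 1, 2 or 3 gave 1160, 525 or 316.

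The mean of the destabilizers against TNF-alpha separates the shared inflammatory response from what each stimulus adds. Interferon-stimulated genes were lower with the destabilizers, 20 of 36 passing the test (26 adjusted over the list alone, 31 with the block on donor), with a mean of -2.05 ± 0.607. CXCL10, an interferon-induced chemokine, was lower by -6.19 ± 0.75 (adjusted p = 0.000196, limma), CXCL11 by -4.76 ± 0.64 and IFI35 by -1.99 ± 0.22. EGR3, an immediate early transcription factor, was higher by 3.36 ± 0.54, STC1, a secreted glycoprotein, by 3.38 ± 0.41, and DUSP1 by 1.96 ± 0.23. ACTN1 was higher by 0.95 ± 0.10.

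The interferon call was lost at adjusted p = 0.0911 with an estimated correlation. Of 16 chemokines 7 were lower and 2 higher (8 and 2 adjusted over the list alone; mean -1.65 ± 0.221; adjusted p = 0.186 with an estimated correlation), and of 22 cholesterol synthesis and uptake genes 7 were lower (14 adjusted over the list alone; mean -0.43 ± 0.126; adjusted p = 0.148 with an estimated correlation), MVK, the mevalonate kinase, by -1.09 ± 0.13. Of 18 NF-kB subunits and feedback genes 8 were lower and 1 higher (10 and 1 adjusted over the list alone; mean -0.51 ± 0.0151; adjusted p = 0.186 with an estimated correlation). MRTF-SRF target genes were higher in 15 of 33 cases (20 adjusted over the list alone; mean 0.72 ± 0.0967; adjusted p = 0.0857 with an estimated correlation), CORO1C, an actin-binding protein, by 0.91 ± 0.12. Immediate early genes were higher in 9 of 23 cases (when adjusted over the list alone 14 were higher and 1 lower; mean 0.85 ± 0.375; adjusted p = 0.0911 with an estimated correlation), and MAPK feedback genes in 8 of 23 (9 adjusted over the list alone; mean 0.60 ± 0.163; adjusted p = 0.0302 with an estimated correlation, 0.0733 with the block on donor added). Endothelial identity genes were higher in 3 of 25 cases and lower in 1 (5 and 2 adjusted over the list alone; mean 0.45 ± 0.106), TIE1 by 0.60 ± 0.06, the list being called with the block on donor (camera, adjusted p = 0.00512) and with equal totals (0.0389) but not in the main fit or with an estimated correlation (0.128, or 0.0733 with the block added). In total 743 genes were higher and 677 lower with the destabilizers than with TNF-alpha (52.3% higher), against 33.3% higher with equal totals. The block on donor gave 4625 calls, DESeq2 2407, and leaving out donor 1, 2 or 3 gave 599, 613 or 380. Blocked on donor, 13 cholesterol genes were lower, 26 MRTF-SRF targets higher, 15 immediate early genes higher and 1 lower, and 14 identity genes higher and 4 lower. Mitochondrially encoded genes averaged 0.28 ± 0.148 here, with 0 of 13 higher (0 adjusted over the list alone, 12 with the block), and ribosomal protein genes -0.17 ± 0.0253, with 0 of 31 lower (0 adjusted over the list alone, 24 with the block). Camera called both (adjusted p = 0.000274 and 1.03e-05), but neither with an estimated correlation (0.356 and 0.440), nor the mitochondrial list with quantile normalization (0.0694).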

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

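The tests with equal totals, of edgeR with the block on donor and of camera with both an estimated correlation and the block were chosen after the results were seen. Over all alternatives, the genes named by the rule kept direction and side of the threshold in 13594 checks, passed only under the alternative in 618, lost the threshold in 1260 and reversed in 1. That was MT-ND3 with vinblastine, 0.30 as deposited and -0.0154 (adjusted p = 0.955, limma) under quantile normalization, which forces equal distributions. Called lists kept their call in 1241 checks and lost it in 299, of which 90 with an estimated correlation, 109 with that and the replicate block, and 40 with quantile normalization. With the block on donor 174 of the named results passed that otherwise did not, and 0 were lost. Camera with the block also called the YAP and TAZ list with docetaxel (adjusted p = 0.0316) and, for destabilizers against TNF-alpha, coagulation (0.0269), junction (0.0178), Notch and BMP (0.0458) and lymphatic genes (0.00186), and did not call microtubule-associated proteins for destabilizers against docetaxel (0.0835). None of the calls gained here held with an estimated correlation, with or without the block. The block moved 160 of 224 counts of list members by over 1.5 times, 160 of them up. Apart from these and the values beside the results, the block at the preset correlation changed no other call of a list. Where no cause is named below, the cause was not tested.

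Counts of changed genes moved as follows. With the donor as a replicate block they were 4881 (TNF-alpha), 6036 (combretastatin A4), 5938 (vinblastine), 5266 (plinabulin), 84 (docetaxel), 5055 (destabilizers against docetaxel) and 4625 (against TNF-alpha), and 4505 genes were called in 1 direction by all 3 destabilizers. edgeR with the replicate block gave 4880, 5977, 5915, 5227, 69, 5029 and 4563, and 4496 for all 3. Both remove the donor differences that otherwise count as residual spread. DESeq2 gave 2684 (TNF-alpha), 2981 (plinabulin), 40 (docetaxel), 4 (combretastatin A4 against vinblastine), 2 (combretastatin A4 against plinabulin), 2 (vinblastine against plinabulin), 2938 (destabilizers against docetaxel) and 2407 (against TNF-alpha). With only the groups compared, and so fewer libraries, counts were 364 (TNF-alpha), 886 (combretastatin A4), 849 (vinblastine), 414 (plinabulin) and 0 (docetaxel, unadjusted p under 0.05 in 572 genes in the full fit). With no filter docetaxel had 5.

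Leaving out a donor removes 6 libraries and gave 441 to 958 genes (TNF-alpha), 859 to 1682 (combretastatin A4), 861 to 1720 (vinblastine), 531 to 1199 (plinabulin), 0 to 2 (docetaxel), 316 to 1160 (destabilizers against docetaxel), 380 to 613 (against TNF-alpha) and 478 to 1075 (all 3 destabilizers). The lowest count came without donor 3 in each of these except docetaxel, which had 0 without donor 2 or 3. Correlations were then 0.454 to 0.524 (docetaxel with TNF-alpha), 0.805 to 0.838 (among destabilizers), 0.545 to 0.569 (destabilizers with docetaxel) and 0.604 to 0.650 (with TNF-alpha), and list counts 10 to 18 (docetaxel).

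Counts of lists with an estimated correlation were 3 (TNF-alpha), 3 (combretastatin A4), 3 (vinblastine), 4 (plinabulin), 2 (docetaxel), 4 (destabilizers against docetaxel) and 1 (against TNF-alpha). With the replicate block added they were 0, 0, 0, 0, 1, 0 and 0, the 1 being the tubulin genes with docetaxel. Quantile normalization gave 10 (combretastatin A4), 8 (vinblastine) and 8 (plinabulin). The mean correlation of changes among destabilizers moved to 0.802 with no filter, 0.927 with the stricter filter, 0.810 with edgeR, 0.730 with DESeq2 and 0.797 with edgeR and the replicate block. That of destabilizers with docetaxel moved to 0.624 (pseudocount 5), 0.543 (no filter), 0.638 (stricter filter) and 0.519 (DESeq2), and that of docetaxel with TNF-alpha to 0.550 (pseudocount 5) and 0.561 (stricter filter).

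With 3 libraries per group and donors that differ, small changes can be missed: limma called 5.97% of simulated 1.5-fold changes in the combretastatin A4 comparison.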

Other observations

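Of the tests below, 5 were chosen only after the results were seen: those of shared controls, of RNA mixing (in place of a test on tubulin genes, which docetaxel raised with or without mixing), of reads moved between tubulin paralogs (2 tests) and of free tubulin. The bound of 0.25 in the paralog tests was set after their values were seen and turned the outcome for the destabilizers from in favour of moved reads to undecided. The tests of other splits, of depth and of GC content and length were set beforehand.

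A minority of the stress genes passed in the main fit with the destabilizers, given in the order combretastatin A4, vinblastine, plinabulin with 3 libraries per group. Of 16 NRF2 target genes 6, 5 and 5 rose and 1, 1 and 1 fell, as when adjusted over the list alone, with the autophagy receptor SQSTM1 at 1.76 ± 0.14, 1.71 ± 0.14 and 1.61 ± 0.14 and OSGIN1 at 2.00 ± 0.25, 1.84 ± 0.25 and 1.53 ± 0.25 (log2 ± SE; adjusted p = 0.388, 0.345 and 0.407 with an estimated correlation). The list was called in the main fit, a call lost with quantile normalization for vinblastine and plinabulin (camera, 0.0607 and 0.0676). Of 14 heat shock genes 6, 6 and 5 rose (6, 6 and 6 adjusted over the list alone), with HSPA6 at 3.03 ± 0.47, 3.12 ± 0.47 and 2.66 ± 0.47 (adjusted p = 0.131, 0.129 and 0.143 with an estimated correlation, and 0.0764, 0.0580 and 0.0692 with quantile normalization, both ending the calls). Of 22 integrated stress and unfolded protein response genes 3, 4 and 2 rose (3, 4 and 2, with 1, 1 and 0 falling, when adjusted over the list alone), TRIB3 by 1.82 ± 0.21, 1.76 ± 0.21 and 1.61 ± 0.21 (adjusted p = 0.392, 0.345 and 0.495 with an estimated correlation, and 0.199, 0.149 and 0.286 with quantile normalization), and plinabulin's list was called with the block on donor (camera, adjusted p = 0.0447) and with equal totals (0.0386) but not in the main fit. Of 22 p53 target genes 5, 5 and 5 rose and 2, 2 and 2 fell (5, 5 and 5, and 3, 3 and 2, adjusted over the list alone): AEN rose by 1.04 ± 0.15, 1.04 ± 0.15 and 0.93 ± 0.15, while DDB2, a DNA damage sensor, changed by -0.66 ± 0.10, -0.63 ± 0.10 and -0.73 ± 0.10. NPC1, which moves cholesterol out of lysosomes, rose by 1.91 ± 0.14, 1.83 ± 0.14 and 1.54 ± 0.14. It was the 1 gene of the 23 on the autophagy and lysosome list to pass in each comparison, also when adjusted over the list alone. SQSTM1 and MAP1LC3B, which also rose, were counted with the NRF2 target genes and the microtubule-associated proteins and not on this list. Of 22 cholesterol genes 3, 4 and 3 rose and 2, 2 and 1 fell, as when adjusted over the list alone, with LSS at 0.58 ± 0.10, 0.62 ± 0.10 and 0.56 ± 0.10. Of 22 hypoxia and glycolysis genes 3, 2 and 2 rose (2, 2 and 2 adjusted over the list alone), the hexokinase HK1 by 0.86 ± 0.13, 0.85 ± 0.13 and 0.76 ± 0.13, and camera called none of the p53, autophagy, cholesterol and hypoxia lists. Under the block on donor the members rising and falling were 9, 8 and 8 against 1, 2 and 2 (NRF2), 9, 10 and 9 against 1, 1 and 1 (integrated stress), 5, 5 and 6 against 7, 8 and 5 (p53), 6, 6 and 5 against 1, 1 and 2 (autophagy and lysosome), 7, 7 and 7 against 5, 3 and 3 (cholesterol) and 8, 8 and 8 against 2, 2 and 2 (hypoxia).

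Few cell cycle genes passed in the main fit. Of 26 G1/S and DNA replication genes 3, 2 and 0 fell and 1, 0 and 0 rose (3, 0 and 0, and 1, 0 and 0, adjusted over the list alone), with means of -0.42 ± 0.298, -0.45 ± 0.301 and -0.35 ± 0.477 (SD over donors) and MCM3, part of the replicative helicase, at -0.55 ± 0.17, -0.57 ± 0.17 and -0.48 ± 0.17 (with plinabulin adjusted p = 0.00308 with the block on donor, not called without). The list was called by camera for the first pair, and for plinabulin with the block on donor (adjusted p = 0.0193), with adjusted p = 0.734, 0.733 and 0.681 with an estimated correlation. The calls for combretastatin A4 and vinblastine ended with equal upper quartiles (0.0898 and 0.0861), quantile normalization (0.142 and 0.141) and equal totals (0.162 and 0.149). Of 33 G2/M and mitotic genes 1, 1 and 0 rose (0, 0 and 0 adjusted over the list alone), with means of 0.33 ± 0.754, 0.45 ± 0.590 and 0.50 ± 0.669 (adjusted p = 0.739, 0.733 and 0.670 with an estimated correlation). Of 22 Notch and BMP target genes 4, 4 and 3 rose and 2, 2 and 2 fell (5, 4 and 5, and 4, 3 and 3, adjusted over the list alone): BMP2 rose by 2.28 ± 0.57, 2.24 ± 0.57 and 1.86 ± 0.57, and BMP4 changed by -2.95 ± 0.50, -2.69 ± 0.50 and -2.43 ± 0.50, and the list was not called. In the fit blocked on donor, 8, 8 and 7 G1/S genes fell and 1, 1 and 1 rose, 9, 7 and 9 G2/M genes rose, and 5, 5 and 5 Notch and BMP targets rose and 6, 5 and 5 fell.

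Other splits of the libraries were tried for each count. A comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 1672 and 1 gene with TNF-alpha, 2667 and 1 with combretastatin A4, 2654 and 1 with vinblastine, 1986 and 0 with plinabulin and 2 and 1 with docetaxel, each with 1 split as large, the real one. Between destabilizers all 10 splits reached the real count of 0, the highest other being 0, 1 and 1. Counts of called lists were exceeded by other splits except with vinblastine: 14 against 17 with TNF-alpha (3 splits as large), 18 against 19 with combretastatin A4 (2), 18 against 17 with vinblastine (1), 16 against 19 with plinabulin (2) and 15 against 18 with docetaxel (3). Splits with 1 library of each donor on each side, as in the real groups, called at most 11, 13, 14, 11 and 10 lists and 1, 0, 1, 0 and 0 genes; the others part donors unequally. For destabilizers against docetaxel 1 of 100 drawn splits, the real one, was as large for genes (1871, highest other 1020, 1 with 1 library of each donor in the small group). Chance is argued against for this count, though the draws include splits that part donors unequally. For lists 11 of 100 were as large (13, highest other 19, also with 1 library of each donor in the small group), so chance cannot be excluded there. Against TNF-alpha 1 of 100, the real one, was as large for genes (1420, highest other 130, 1 with 1 library of each donor in the small group), so chance is argued against with the same limit. For lists 3 of 100 were (16, highest other 16), but a split with 1 library of each donor in the small group also reached 16, so the count of lists does not stand out among such splits.

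In the median, docetaxel moved the genes shared by the destabilizers the same way but less far. The shared controls are argued against as the whole cause, since over genes higher with all 3 destabilizers in 2 donors the median docetaxel change in the remaining donor, whose DMSO library had no part in the choice, averaged 0.288 (log2, SD 0.0292). This test replaced an earlier one after the values of the earlier one were seen. The earlier one compared the median docetaxel change of 0.247 with docetaxel simulated as unchanged on shared simulated controls, which reached at most 0.0262. Destabilizer RNA mixed into the docetaxel libraries would give all shared genes 1 share, and the share implied in the remaining donor was 0.216 for higher and 0.301 for lower genes, a difference of 0.0851 (SD 0.0801). This difference is too variable to decide, so mixing and a smaller response of the same kind to docetaxel, which was not tested, cannot be told apart. Single genes and donors departed from the median. In donors 1, 2 and 3 SELE changed by 2.96, 2.12 and 2.32 with docetaxel, against 3.03, 4.93 and 5.74 with combretastatin A4. ACTN1 changed by 0.06, 0.25 and -0.01 with docetaxel, against 1.04, 1.11 and 0.91 with combretastatin A4.

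Genes at low levels tended to negative and genes at high levels to positive changes with TNF-alpha and the destabilizers, the medians of the lowest and highest of 5 equal groups by level differing by 0.37 (log2, SD 0.0707 over donors). Depth is argued against, since 98.6% of the gap stayed after thinning all libraries to equal reads. A trend on GC content and transcript length is argued against as well, with 101% of the gap kept after its removal. A test of a few very abundant genes, set beforehand, also left most of the gap and was dropped after its value was seen, because leaving genes out changes no other gene under fixed size factors; no biological explanation was tested.

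Alpha- and beta-tubulin genes as a list were higher with docetaxel, by 1.42 (log2, SD 0.124 over donors) than with the destabilizers, which left most members without a call in the main fit. Reads moved between near-identical paralogs cannot explain the rise of the family as a whole with docetaxel. The summed alpha- and beta-tubulin values changed by 1.27 (SD 0.394 over donors). The sum is dominated by abundant members, so it does not show that a member at low levels rose itself. TUBB2B, for example, averaged 53.6 normalised read counts with DMSO, and TUBB2A 901. For the destabilizers the sum changed by -0.30 (SD 0.404), which is too variable to decide, so moved reads and real changes cannot be told apart there. A candidate explanation is the known control of alpha- and beta-tubulin mRNA by free tubulin: docetaxel minus destabilizers was larger for alpha and beta tubulins than for gamma, delta and epsilon tubulins by 1.05 (SD 0.178; 1.08 without TUBA8, SD 0.175). The gamma, delta and epsilon genes themselves differed by 0.37 (SD 0.135), which this explanation does not predict. Against DMSO, members went both ways with combretastatin A4, vinblastine and plinabulin. TUBB changed by -0.75, -0.93 and -0.91, but TUBB2B by 1.23, 1.21 and 0.74. TNF-alpha, which is not a microtubule compound, raised the tubulin list by 0.58 on average. Free tubulin predicts neither the rise of TUBB2B with the destabilizers nor that of the list with TNF-alpha.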
